A study of Mus musculus with 38 samples.

How the data were processed

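Livers of male CD-1 mice, an outbred stock, were profiled on Affymetrix mouse 430 2.0 arrays, 1 array per animal and 38 arrays in all. The arrays belonged to 2 feeding experiments, each with its own controls. In the conazole experiment, control diet, propiconazole at 2500 ppm and triadimefon at 1800 ppm were given for 4 or 30 days, with 3 animals per group. Both conazoles are triazoles, agricultural fungicides that inhibit fungal sterol 14-demethylase. In the phenobarbital experiment, control diet and phenobarbital at 850 ppm were given for the same times, with 5 animals per group. Phenobarbital is a barbiturate used as the reference activator of the nuclear receptor CAR in rodent liver. Groups and replicate numbers were taken from the sample labels, which say biological replicates. No pair of arrays held identical values. Because the experiments had separate controls, experiment and array batch cannot be told apart, and a conazole was set against phenobarbital only as a difference between each compound's change from its own controls.

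Per the labels' protocols, the mice were 6 to 8 weeks old, total RNA was extracted with Tri Reagent and cleaned on RNeasy columns, and 4 ug was amplified and labelled with biotin by an Enzo kit. The software that summarised and scaled the probe sets is not given in the sources used here. The deposited values were 1 linear intensity per probe set and array, of which 21.15% were below 0, as background subtraction leaves them. The values as deposited shared no common scale: medians ran from 12.5 to 36.1 between arrays and the 2 experiments differed in their upper range. The design fixed before the data were examined had taken the values as deposited as the main setting, with quantile normalization as an alternative. These were exchanged once the scales were seen, and the values as deposited became an alternative.

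Intensities of the 38 arrays were quantile normalized, values below 0 were set to 0, and log2(value + 16) was taken, so that the lowest possible value was 4. A change is a difference on this scale and understates the change of dim genes. The platform annotation listed 35890 of the 45101 probe sets. Of these, 34945 carried 1 gene symbol and 932 several, while 9211 were unlisted and are unnamed here. Only probe sets with 1 symbol were used, giving 18193 genes, and 9010 genes with several probe sets were represented by the probe set with the highest mean. After 465 genes with the same value on all arrays were left out, 17728 genes were tested. No symbol needed updating against the reference gene table (GRCm38.p6), which was used for names only.

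Arrays give no read depth, and the number of animals and the signal over background limit the precision. Background was the 95th percentile of the means of 39 olfactory receptor genes, a log2 value of 6.13 or an intensity of 54.2, and 9313 genes had a mean above it. A gene below background on every array of a group has only a bound there. Its difference is given as at least N-fold, the mean of the brighter group against the dimmer group's mean of the higher of background and the gene's own value, and no fold is given where both groups were below background or the ratio fell under 1. Where only some arrays of a group were above background, their number is given as the arrays that measured the gene, except in differences of changes and counts of list members.

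A linear model with 1 mean per group was fitted to all 38 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step (28 residual and 2.91 prior degrees of freedom). All groups thereby shared 1 estimate of each gene's spread. The 15 two-sided comparisons were each compound against its control on each day, propiconazole against triadimefon on each day, each compound's day 30 change minus its day 4 change, and each conazole's change minus the phenobarbital change on each day. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p below is from these limma fits or, for lists, from limma's camera. Errors of changes are standard errors, and errors of group means are SDs.

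Fixed before the data were examined were 33 gene lists, of whose 536 genes 479 were measured. Some genes stand in more than 1 list. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. In all 114 list tests that passed with the preset correlation, median, mean and test had the same sign.

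Genes are named by a rule fixed in advance: for each compound against control, the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between the groups, and for the other comparisons 5 of each, without the overlap condition where effects were compared. Genes known only by clone, Riken, Gm, LOC or EST names and probe sets that cross-hybridise (_x_at) were left out. Members of the fixed lists were also named, the up to 4 largest called members of a described list first.

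The overlap of calls between compounds with the same controls was set against simulated unchanged groups and against independent lists of the same sizes. The alternatives fixed in advance were the values as deposited, median centring, a pseudocount of 64, 2 filters on dim genes, the mean of a gene's probe sets, every probe set, leaving out probe sets of the _x_at and _s_at kinds, eBayes without trend or with a robust trend, array weights, a fit on only the arrays compared, the replicate number as a block, and leaving out each array in turn, with stricter thresholds for overlaps and an estimated correlation for lists. Added after the data were seen were quantile normalization within each experiment, fits without 1 array of doubtful RNA quality (propiconazole day 4 replicate 2), and list tests with each array left out.

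The fit was tested on simulated data of 9670 genes, 200 of them changed by log2 0.58, 1 or 2. For propiconazole on day 4 it recovered 26.9%, 62.7% and 92.4% of them, with 6 false calls among 132. For phenobarbital on day 4 the shares were 55.2%, 89.6% and 97.0%, with 8 false calls among 183. For the difference between both changes they were 17.9%, 64.2% and 97.0%, with 2 false calls among 123. Real day 4 SDs between arrays were 0.516 for propiconazole and 0.246 for phenobarbital, so the shares hold for the simulation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.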

Results

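Livers of male CD-1 mice were profiled to ask how 2 triazole fungicides and phenobarbital change transcripts after 4 and 30 days in the diet. The conazole experiment held 6 groups of 3 animals and the phenobarbital experiment 4 groups of 5. The labels give intakes of 349.6 ± 46.7, 257.1 ± 33.5 and 97.2 ± 5.9 mg/kg/day for propiconazole, triadimefon and phenobarbital. The doses were not matched. Changes are on the log2(intensity + 16) scale after quantile normalization.

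The median deposited intensity was 12.5 to 34.5 on conazole arrays and 25.0 to 36.1 on phenobarbital arrays, and the highest intensity was 8822 to 11270 and 14880 to 17990. One array, propiconazole day 4 replicate 2, had the lowest median (12.5) and a Gapdh signal at the 3′ end that exceeded the signal at the 5′ end by 6.40 log2 units, against -0.35 to 0.22 on the other 37 arrays. Its Actb difference was 1.84, against at most 1.37 elsewhere, while its Tfrc difference of 0.78 was the lowest of all arrays (others 1.22 to 2.83). A large 3′ excess is a sign of short or degraded RNA. The 3 propiconazole day 4 arrays correlated with their own group at a mean r of 0.79 to 0.86 across 7074 genes, and all other arrays at 0.9555 or more. Because all groups shared 1 estimate of the spread, this array also entered the errors of the other comparisons, and counts without it are given with each comparison. The Actb 3′ excess also moved with day and group: its mean was 1.12 in conazole controls, 1.17 under propiconazole and 0.82 under triadimefon on day 4, 0.40, 0.42 and 0.49 on day 30, and 0.34 to 0.36 in the phenobarbital experiment.

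**Figure D1:**
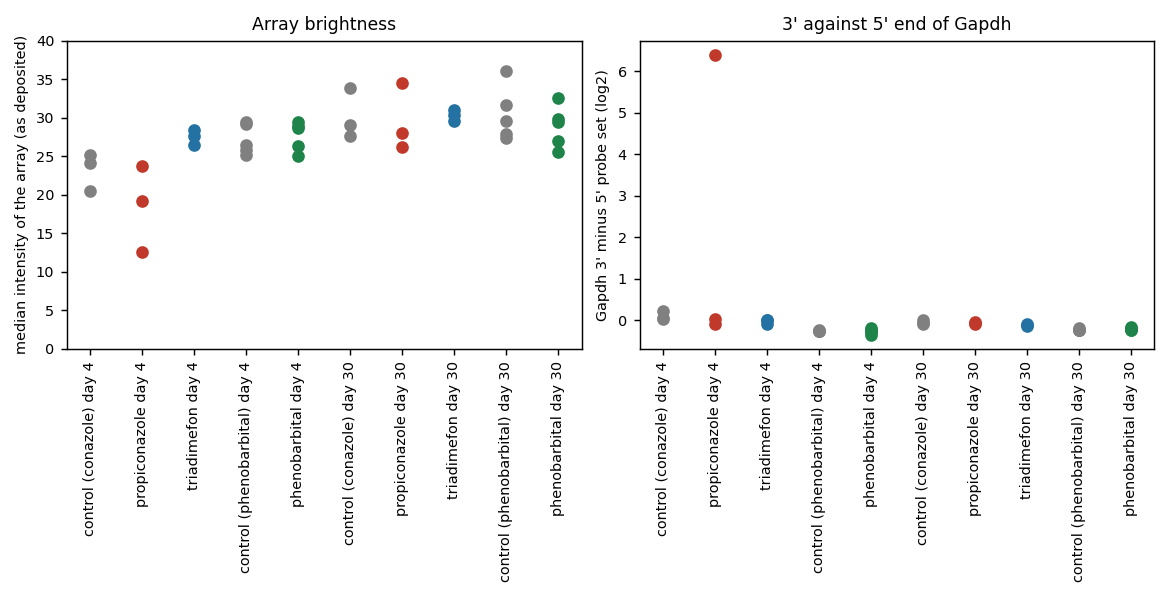
Median deposited intensity (linear scale) and the Gapdh 3′ minus 5′ signal (log2) of each of the 38 arrays by group, 1 point per array. Propiconazole day 4 replicate 2 has the lowest median and the highest difference.

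In propiconazole livers on day 4, drug-metabolising enzymes rose most. Cyp2c55 stood at 12.65 ± 0.44 against 7.07 ± 0.47 in controls (SD, n = 3 each), a rise of 5.58 ± 0.32 (47.7-fold, adjusted p = 2.2e-13). Cyp2b10, the classical CAR target, rose by 4.80 ± 0.45 (27.8-fold, adjusted p = 2.2e-08), and Alas1, the rate-limiting enzyme of heme synthesis, by 3.85 ± 0.43 (adjusted p = 1.1e-06). Cyp2c65 was at least 6.23-fold and Gadd45b, a stress-inducible signalling protein, at least 4.13-fold higher (adjusted p = 6.1e-09 and 1.0e-04), both below background in controls. In all, 1305 genes were higher and 1158 lower (221 and 2376 with values as deposited, 575 and 1177 with median centring). Of the 17 CYP2B, CYP2C and CYP3A enzymes measured, 8 rose, 0 fell and 9 did not pass (9 rose adjusted over the list alone, list adjusted p = 1.1e-08). The other CAR and PXR responsive genes had 8 of 12 higher and Nr1i3, which encodes CAR itself, lower by -2.20 ± 0.59 on 2 of 3 treated arrays (10 and 1 adjusted over the list alone, list adjusted p = 7.2e-07). Both lists held with an estimated correlation (adjusted p = 0.016 each). Among glutathione S-transferases 5 of 19 rose and 2 fell (6 and 3 adjusted over the list alone, list adjusted p = 0.064; 4 rose and 0 fell, adjusted p = 0.0062, without replicate 2), led by Gstt3 (3.32 ± 0.46, adjusted p = 3.1e-05) and Gstm3 (1.51 ± 0.15). Of 18 UDP-glucuronosyltransferases and sulfotransferases 6 rose and 0 fell (7 adjusted over the list alone, list adjusted p = 0.014, 0.11 with an estimated correlation), with Sult1c2 at 1.45 ± 0.33. Of 8 AHR responsive genes Ahr alone rose (1.43 ± 0.19; 2 adjusted over the list alone, list adjusted p = 0.031, 0.11 with an estimated correlation). Without replicate 1 of propiconazole the AHR list (adjusted p = 0.21) and the conjugation list (0.11) lost their calls. Without replicate 2, the array with the 3′ excess, Nr1i3 was no longer called (-0.66, adjusted p = 0.0503).

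Stress and cell cycle transcripts were also higher in propiconazole livers on day 4. Of 11 heat shock proteins 5 rose and 0 fell (11 adjusted over the list alone, list adjusted p = 8.4e-06, 0.27 with an estimated correlation), among them the chaperones Hspa1b (2.53 ± 0.62, adjusted p = 0.0066) and Dnajb1 (1.46 ± 0.36). In the unfolded protein and integrated stress response 5 of 19 rose and 0 fell (6 adjusted over the list alone, list adjusted p = 0.014, 0.37 with an estimated correlation). The stress transcription factor Atf3 was at least 1.38-fold higher, measured on 2 of 3 treated arrays, and Ddit3 rose by 1.70 ± 0.30 (adjusted p = 4.7e-04, measured on 2 of 3 control arrays) and the co-chaperone Dnajb9 by 1.61 ± 0.24. Cell cycle genes had 8 of 34 higher and 1 lower (11 and 1 adjusted over the list alone, list adjusted p = 1.8e-04, 0.34 with an estimated correlation). Their largest rises, Birc5 and Mki67, have no fold because their means were below background, and both rested on replicate 2 (adjusted p = 0.13 and 0.25 without it). NRF2 responsive genes had 5 of 15 higher and 1 lower (8 and 1 adjusted over the list alone, list adjusted p = 0.011, 0.34 with an estimated correlation), with Abcc4 at least 1.16-fold higher on 2 of 3 arrays. S100a8, a calcium-binding protein of myeloid cells, was at least 15.9-fold and Orm3, an acute phase glycoprotein, at least 2.89-fold higher (adjusted p = 0.018 and 0.034), the latter on 2 of 3 arrays. Of 24 acute phase proteins 4 rose and 0 fell (4 adjusted over the list alone, list adjusted p = 0.52), but without replicate 2, 0 rose and 3 fell. Leaving out replicate 2 also ended the calls of S100a8 (adjusted p = 0.13), Orm3 (0.26) and Abcc4 (0.069), and left 3 cell cycle and 5 other CAR and PXR responsive genes higher. Without replicate 1 of propiconazole the NRF2 (0.66), cell cycle (0.12) and unfolded protein lists (0.21) lost their calls.

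Among genes lower in propiconazole livers on day 4, Ppara, the nuclear receptor for fatty acids, stood at 8.39 ± 1.10 against 10.73 ± 0.09 in controls (-2.34 ± 0.33, adjusted p = 3.1e-05), and Ppargc1b, a coactivator of mitochondrial genes, fell by 3.50 ± 0.43 (adjusted p = 4.2e-06, measured on 1 of 3 treated arrays). The immediate early factors Egr1 and Junb changed by -3.39 ± 0.90 and -2.56 ± 0.60 (adjusted p = 0.012 and 0.0049, Junb measured on 1 of 3 treated arrays), and the Egr1 corepressor Nab2 was at least 1.96-fold lower. The noncoding Hectd2os (-3.09 ± 0.78), Fam20a (-2.87 ± 0.61) and the phospholipase Plcg1 (-2.30 ± 0.52) completed the largest falls, measured on 1, 1 and 2 of 3 treated arrays. Of 25 PPAR-alpha targets and fatty acid oxidation genes 9 fell and 0 rose (9 adjusted over the list alone, list adjusted p = 8.1e-07, 0.11 with an estimated correlation), including the beta-oxidation enzyme Acadvl (-0.97 ± 0.24, but -0.36 without replicate 2). Bile acid synthesis genes had 1 of 14 higher and 2 lower (1 and 4 adjusted over the list alone, list adjusted p = 0.043, 0.34 with an estimated correlation). Of 20 cholesterol biosynthesis genes 3 rose and 2 fell (4 and 3 adjusted over the list alone, list adjusted p = 0.87). Pericentral hepatocyte markers had 1 of 14 higher and 1 lower (the same counts adjusted over the list alone, list adjusted p = 0.043, 0.34 with an estimated correlation). Without replicate 2 the bile acid list (adjusted p = 0.30), the pericentral list (0.34) and Plcg1 (0.0504) lost their calls, and without replicate 1 Hectd2os (0.0507). Both lists were also lost without some other arrays (adjusted p up to 0.22 and 0.17). Without replicate 2, 1644 genes were called, of which 1074 were among the 2463. The fit on only the 6 arrays compared called 6 genes, Alas1, Cyp2b10, Cyp2c55, Cyp2c65, Gadd45b and Stbd1, against 1629 at an unadjusted p under 0.05. Without control replicate 2 the count was 1526, and without propiconazole replicate 3 it was 3856.

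After 30 days of propiconazole the drug-metabolising enzymes were higher again. Cyp2c55 rose by 6.00 ± 0.32 and Cyp2b10 from 7.11 ± 1.70 to 13.05 ± 0.02, or 5.94 ± 0.45 (adjusted p = 2.7e-14 and 1.5e-10, both measured on 2 of 3 control arrays). Cyp2c65 was at least 16.8-fold, Cyp2b13 at least 10.6-fold and Gadd45b at least 8.63-fold higher (adjusted p = 8.1e-12, 1.5e-05 and 3.6e-06). The actin-binding protein Nebl was at least 12.7-fold higher (adjusted p = 4.3e-06). In all, 937 genes were higher and 980 lower. Of 17 CYP2B, CYP2C and CYP3A enzymes 10 rose and 0 fell (11 adjusted over the list alone, list adjusted p = 1.5e-15, 9.7e-04 with an estimated correlation). Of 12 other CAR and PXR responsive genes 8 rose and 0 fell (9 and 1 adjusted over the list alone, list adjusted p = 3.2e-09, 0.0032 with an estimated correlation). They included the bile salt and drug uptake carrier Slco1a4 (2.92 ± 0.58) and Alas1 (1.36 ± 0.43, adjusted p = 0.040). Glutathione S-transferases had 6 of 19 higher (9 and 1 lower adjusted over the list alone, list adjusted p = 2.3e-04, 0.13 with an estimated correlation), with Gstt3 at 3.11 ± 0.46 and Gstm2 at 2.17 ± 0.33. UDP-glucuronosyltransferases and sulfotransferases had 6 of 18 higher and 1 lower (7 and 2 adjusted over the list alone, list adjusted p = 0.0015, 0.045 with an estimated correlation), with Sult1c2 at least 6.31-fold higher. NRF2 responsive genes had 6 of 15 higher and 0 lower (6 adjusted over the list alone, list adjusted p = 1.8e-05, 0.10 with an estimated correlation). The efflux pump Abcc4 was at least 8.72-fold higher, and the reductases Cbr3 and Nqo1, each measured on 2 of 3 treated arrays, at least 1.88-fold and 1.55-fold. Of 16 p53 targets 3 rose and 0 fell (4 adjusted over the list alone, list adjusted p = 0.023, 0.17 with an estimated correlation), led by Fas (0.86 ± 0.24, measured on 2 of 3 control arrays) and the epoxide hydrolase Ephx1 (0.73 ± 0.17). With 1 array left out, the calls ended for Alas1 (adjusted p = 0.19, control replicate 3) and, without propiconazole replicate 1, for Fas (0.14) and the p53 list (0.086).

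Male-biased and female-biased liver genes also changed on day 30 of propiconazole. Of 12 male-biased liver genes 5 fell and 0 rose (5 adjusted over the list alone, list adjusted p = 1.2e-05, 0.10 with an estimated correlation). Susd4 was at least 9.90-fold lower (adjusted p = 3.2e-08). The steroid reductase Hsd3b5 stood at 7.9 ± 3.0 against 11.98 ± 0.17 in controls (-4.09 ± 0.77, adjusted p = 7.1e-04, measured on 2 of 3 treated arrays, but -2.36 without replicate 3). The error of 0.77 comes from the shared spread and understates the SD of 3.0 among the treated arrays. Of 14 female-biased genes 5 rose and 1 fell (7 and 1 adjusted over the list alone, list adjusted p = 6.3e-04, 0.10 with an estimated correlation). Besides Cyp2b13, Cyp2b9 rose by 3.85 ± 0.69 (measured on 1 of 3 control arrays) and Prom1 at least 4.80-fold. Obp2a was at least 10.9-fold lower (adjusted p = 1.9e-05), Hectd2os at least 5.65-fold and Serpina9 at least 2.88-fold lower. Enho, which encodes the secreted peptide adropin, Rdh16f2 and Serpina4-ps1 changed by -3.68 ± 0.56, -3.47 ± 0.59 and -3.34 ± 0.60, Enho (3 of 4 probe sets) on 1 and Rdh16f2 on 2 of 3 treated arrays. Lcn2, an iron-sequestering acute phase protein, was at least 18.4-fold, Orm3 at least 10.4-fold and S100a8 at least 13.4-fold higher (adjusted p = 0.0042, 0.0025 and 0.011), S100a8 on 2 of 3 arrays. The acute phase list had 3 of 24 higher and 2 lower (the same counts adjusted over the list alone, list adjusted p = 0.35). Pericentral markers had 4 of 14 lower and 0 higher (8 lower and 1 higher adjusted over the list alone, list adjusted p = 0.0014, 0.17 with an estimated correlation), among them Axin2 (at least 1.24-fold, measured on 2 of 3 control arrays) and Oat (-1.53 ± 0.31). Bile acid synthesis had 1 of 14 higher and 3 lower (1 and 5 adjusted over the list alone, list adjusted p = 0.023, 0.17 with an estimated correlation). Fatty acid and triglyceride synthesis had 5 of 20 higher and 2 lower (6 and 2 adjusted over the list alone, list adjusted p = 0.069). The cholesterol biosynthesis list lay lower (list adjusted p = 0.012, 0.49 with an estimated correlation) and the Kupffer cell and macrophage list higher (0.0050, 0.49 with an estimated correlation), with 0 members called in each (0 and 3 adjusted over the list alone).

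With 1 array left out, calls lost on day 30 of propiconazole were S100a8 (adjusted p = 0.083) without propiconazole replicate 2, the bile acid list (0.071) and the Kupffer cell list (0.12) without replicate 1, and Axin2 (0.059) without replicate 3. Without control arrays, lost were the bile acid (0.057) and cholesterol lists (0.15) without replicate 3. The count of 1917 fell to 1277 without control replicate 3. Without the day 4 array with the 3′ excess in the shared fit, 2803 genes were called, all 1917 among them. The fit on the 6 arrays compared called 541.

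Triadimefon on day 4 raised several P450 enzymes, several glutathione S-transferases and several genes of cholesterol biosynthesis. Cyp2c55 rose by 5.24 ± 0.32, Cyp2b10 from 8.21 ± 0.67 to 12.64 ± 0.51, or 4.43 ± 0.45, and Alas1 by 3.24 ± 0.43 (adjusted p = 1.2e-12, 2.4e-07 and 4.0e-05). Of 20 cholesterol biosynthesis genes 8 rose, 0 fell and 12 did not pass (14 adjusted over the list alone, list adjusted p = 3.7e-10, 0.13 with an estimated correlation). The mevalonate kinase Mvk stood at 8.25 ± 0.64 against 5.76 ± 1.62 in controls (2.49 ± 0.54, adjusted p = 0.0078, measured on 1 of 3 control arrays), the squalene epoxidase Sqle rose by 1.45 ± 0.30, the isomerase Idi1 by 1.19 ± 0.28 and the lanosterol synthase Lss by 1.16 ± 0.32. Cyp51, the mammalian sterol 14-demethylase, rose by 0.96 ± 0.25 (adjusted p = 0.023). In all, 373 genes were higher and 292 lower (1545 and 114 as deposited, 563 and 174 with median centring), and the Actb 3′ excess was 0.73 to 0.89, against 0.88 to 1.37 in controls. The retinoic acid hydroxylase Cyp26a1 rose by 2.86 ± 0.48, Gstt3 by 3.15 ± 0.46, Cyp2c37 by 2.71 ± 0.48 (measured on 2 of 3 control arrays) and the nucleotidase Entpd6 by 2.84 ± 0.71 (1 of 3). Gadd45b was at least 2.13-fold higher on 2 of 3 arrays and in 2 of 3 probe sets. The largest falls were Egr1 (-3.42 ± 0.90, adjusted p = 0.028), the interleukin-1 receptor Il1r1 (-2.62 ± 0.58, a direction that 1 of its 2 probe sets showed) and Neurl4 (-2.44 ± 0.52), the last 2 measured on 1 and Egr1 on 2 of 3 treated arrays. Nab2, Cnga2, Ust, Ing2 and Plcb3 were at least 1.96-, 1.21-, 1.18-, 1.17- and 1.07-fold lower, Ust in 1 of 2 probe sets, measured on 3, 2, 2, 1 and 1 of 3 control arrays. Without control replicate 2 Mvk (1.61, adjusted p = 0.087) and Entpd6 (0.12) lost their calls. Without triadimefon replicate 1 the same held for Sqle (1.26, 0.053), Idi1 (0.063), Lss (0.17), Gadd45b (0.054), Egr1 (0.16), Il1r1 (0.083) and Neurl4 (0.078).

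In triadimefon livers on day 4, 6 of 17 CYP2B, CYP2C and CYP3A enzymes rose and 0 fell (9 and 1 adjusted over the list alone, list adjusted p = 3.7e-10, 0.0083 with an estimated correlation), Cyp2c65 at least 1.31-fold on 2 of 3 arrays. Of 12 other CAR and PXR responsive genes 5 rose and 0 fell (10 adjusted over the list alone, list adjusted p = 3.7e-10, 0.0032 with an estimated correlation). Of 19 glutathione S-transferases 6 rose and 0 fell (8 adjusted over the list alone, list adjusted p = 4.8e-05, 0.13 with an estimated correlation), with Gstm3 at 1.44 ± 0.15 (adjusted p = 6.4e-07). Of 15 NRF2 responsive genes 2 rose and 0 fell, among them Nqo1 (at least 1.47-fold; 3 adjusted over the list alone, list adjusted p = 0.0093, 0.40 with an estimated correlation). Of 25 PPAR-alpha targets 2 fell and 0 rose, among them Ppara (-1.35 ± 0.33; 4 adjusted over the list alone, list adjusted p = 0.0036, 0.40 with an estimated correlation). Of 14 markers of sinusoidal endothelium, 3 fell and 0 rose, among them Clec4g (-0.82 ± 0.20, 1 of 2 probe sets) and Ptprb (-0.81 ± 0.16, 2 of 3; 7 adjusted over the list alone, list adjusted p = 1.1e-04, 0.22 with an estimated correlation). The heat shock list lay higher (0 called, 1 adjusted over the list alone, list adjusted p = 0.0029, 0.40 with an estimated correlation). So did the cell cycle list (Aurka alone called, below background in both groups, list adjusted p = 0.0093, 0.54 with an estimated correlation). The male-biased list lay lower (0 called, list adjusted p = 0.011, 0.40 with an estimated correlation). Without triadimefon replicate 2 the calls of the NRF2 (0.12), cell cycle (0.70) and male-biased lists (0.15; 0.13 without control replicate 3) and Nqo1 (0.068) ended. Without triadimefon replicate 1 those of Ppara (0.15) and Aurka (0.14) ended, and without control replicate 1 that of Clec4g (0.13). The count of 665 fell to 215 without triadimefon replicate 1, 327 without control replicate 2 and 437 without control replicate 1. Without the array with the 3′ excess in the shared fit it was 1270, with all 665 among them. The fit on the 6 arrays compared called only Cyp2c55, against 2539 genes at an unadjusted p under 0.05.

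After 30 days of triadimefon, acute phase and macrophage transcripts were higher beside the P450 enzymes. Lcn2 stood at 10.99 ± 1.96 and was at least 29.0-fold higher than in controls, S100a8 at least 17.7-fold and Orm3 at least 8.11-fold (adjusted p = 0.0037, 0.012 and 0.0095), and Orm2 rose by 3.82 ± 1.16 (adjusted p = 0.048). Of 24 acute phase proteins 4 rose and 0 fell (7 adjusted over the list alone, list adjusted p = 1.6e-07, 0.40 with an estimated correlation), the fourth being the C-reactive protein Crp (0.56 ± 0.12). Of 14 Kupffer cell and macrophage markers 6 rose, 0 fell and 8 did not pass (12 adjusted over the list alone, list adjusted p = 1.5e-09, 0.18 with an estimated correlation). The scavenger receptors Timd4 and Marco were at least 2.23-fold and 1.37-fold higher, each measured on 2 of 3 treated arrays. The complement component C1qc rose by 1.49 ± 0.34 and the macrophage surface marker Adgre1 by 1.13 ± 0.23 (adjusted p = 0.0033). In all, 427 genes were higher and 531 lower. Cyp2b10 rose by 5.71 ± 0.45 and Cyp2c55 by 5.60 ± 0.32 (both measured on 2 of 3 control arrays). Cyp2c65 was at least 9.03-fold and Gadd45b at least 3.66-fold higher. The largest falls were Obp2a (at least 10.9-fold, adjusted p = 0.0011), the fatty acid hydroxylase Cyp2u1 (at least 3.83-fold), the phospholipase Pla1a (at least 3.69-fold) and Serpina9 (at least 2.88-fold). They were followed by Serpina4-ps1 (-2.78 ± 0.60), Susd4 (-2.74 ± 0.45, measured on 2 of 3 treated arrays), Aldh3b2 (at least 1.39-fold) and Asic1 (at least 1.38-fold, measured on 2 of 3 control arrays). With 1 array left out the calls of Orm3 (adjusted p = 0.057), Orm2 (0.19) and Marco (0.12) ended without triadimefon replicate 3, and those of Timd4 (0.17) and C1qc (0.087) without replicate 1.

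On day 30 of triadimefon 7 of 17 CYP2B, CYP2C and CYP3A enzymes rose and 0 fell (8 adjusted over the list alone, list adjusted p = 2.2e-15, 0.0010 with an estimated correlation). Of 12 other CAR and PXR responsive genes 5 rose and 0 fell (8 adjusted over the list alone, list adjusted p = 1.1e-08, 0.0050 with an estimated correlation). Glutathione S-transferases had 4 of 19 higher and 0 lower (4 and 1 adjusted over the list alone, list adjusted p = 0.025, 0.40 with an estimated correlation), with Gstt3 at 2.67 ± 0.46 and Gstm3 at 1.73 ± 0.15. UDP-glucuronosyltransferases and sulfotransferases had 6 of 18 higher and 0 lower (6 adjusted over the list alone, list adjusted p = 0.0038, 0.067 with an estimated correlation). Of 12 male-biased genes 3 fell and 0 rose (6 adjusted over the list alone, list adjusted p = 1.2e-04, 0.25 with an estimated correlation). The glutathione S-transferase list was no longer called without control replicate 2 (adjusted p = 0.13), and the conjugation list without triadimefon replicate 2 (0.074). The count of 958 fell to 502 without triadimefon replicate 1 and 599 without control replicate 1. It rose to 1699, with all 958 among them, without the day 4 array with the 3′ excess. The fit on the 6 arrays compared called 118.

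Phenobarbital on day 4 raised P450 enzymes most. Cyp2c55 rose from 7.32 ± 0.38 to 12.44 ± 0.15 (SD, n = 5 each), or 5.12 ± 0.25 (adjusted p = 1.6e-15). Cyp2b10 rose from 9.23 ± 0.30 to 12.79 ± 0.05, or 3.56 ± 0.35, and Cyp2c37 by 2.18 ± 0.37 (adjusted p = 3.9e-08 and 0.0011). Cyp2c65 was at least 6.16-fold, Gadd45b at least 3.19-fold, Cyp2g1 at least 2.90-fold, the kinetochore protein Nsl1 at least 2.23-fold and Thap6 at least 2.21-fold higher. In all, 94 genes were higher and 26 lower. Of 17 CYP2B, CYP2C and CYP3A enzymes 6 rose and 0 fell (8 adjusted over the list alone, list adjusted p = 3.0e-20). Of 12 other CAR and PXR responsive genes 4 rose and 0 fell (7 adjusted over the list alone, list adjusted p = 4.7e-17). Both stood at adjusted p = 7.0e-05 with an estimated correlation. Of 19 glutathione S-transferases 5 rose (10 adjusted over the list alone, list adjusted p = 3.1e-12, 0.0026 with an estimated correlation), led by Gstm2 (2.11 ± 0.25) and Gstm3 (1.71 ± 0.12). Of 18 UDP-glucuronosyltransferases and sulfotransferases 4 rose (6 adjusted over the list alone, list adjusted p = 2.5e-07, 5.0e-04 with an estimated correlation), led by Sult1c2 (1.19 ± 0.26) and Ugt2b34 (0.60 ± 0.06). Of 34 cell cycle genes Birc5, Ccnb2 and Kif20a were called higher and 0 lower (16 adjusted over the list alone, list adjusted p = 1.7e-14, 0.039 with an estimated correlation), with no fold because their means were at or below background. Of 16 p53 targets Ephx1 rose (0.74 ± 0.13; 3 adjusted over the list alone, list adjusted p = 6.0e-04, 0.043 with an estimated correlation). The gluconeogenesis and glucocorticoid responsive list lay lower (0 of 15 called, 2 adjusted over the list alone, list adjusted p = 4.0e-04, 0.032 with an estimated correlation). The largest falls were the homeobox factor Hhex (-1.10 ± 0.25), the choline kinase Chka (-0.95 ± 0.22), and the EGF receptor inhibitor Errfi1 (-0.79 ± 0.17). Next came the ribonuclease Ang (-0.75 ± 0.16), the sterol transporter Abcg5 (-0.73 ± 0.16) and Glt28d2 (-0.70 ± 0.17, on 4 of 5 treated arrays), besides Spns3 and Kcng2 at or below background. With 1 array left out the calls ended of Hhex (adjusted p = 0.087, control replicate 1), Chka (0.11, phenobarbital replicate 5), Errfi1 (0.065), Ang (0.075) and Glt28d2 (0.18, all without phenobarbital replicate 3), Abcg5 (0.11, phenobarbital replicate 2), Cyp2g1 (0.14, control replicate 2) and Sult1c2 (0.068, phenobarbital replicate 1).

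Further lists passed on day 4 of phenobarbital with the preset correlation and not with the estimated one, with 0 members called. Higher were the NRF2 responsive genes (adjusted p = 0.0050, then 0.29 with an estimated correlation), heat shock proteins (0.039, then 0.53) and the unfolded protein response (0.021, then 0.47, with 1 higher and 2 lower adjusted over the list alone). Lower were cholesterol biosynthesis (adjusted p = 0.0056, then 0.47), fatty acid and triglyceride synthesis (0.022, then 0.47) and pancreatic acinar markers (1.1e-04, then 0.40). The acute phase proteins were also lower (0.0056, then 0.53, with 1 higher and 2 lower adjusted over the list alone). The acinar call rested on 1 control animal, replicate 1, without which the list adjusted p was 0.98. Without control replicate 3 the cholesterol (0.30), fatty acid (0.57) and unfolded protein lists (0.21) lost their calls, without control replicate 2 the acute phase list (0.31) and without phenobarbital replicate 1 the heat shock list (0.19). The count of 120 fell to 65 without control replicate 1, 69, 70 and 75 without phenobarbital replicates 3, 5 and 2. It rose to 248, with all 120 among them, without the conazole array with the 3′ excess. The fit on the 10 arrays compared called 330.

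After 30 days of phenobarbital Cyp2c55 rose by 5.20 ± 0.25, Cyp2b10 by 4.09 ± 0.35, Cyp2b9 by 3.14 ± 0.54 and Cyp2c37 by 3.02 ± 0.37 (adjusted p = 1.1e-15, 1.7e-09, 0.0013 and 6.0e-06, with Cyp2b9 measured on 1 and Cyp2c37 on 4 of 5 control arrays). Cyp2c65 was at least 18.5-fold, Moxd1, a monooxygenase, at least 7.72-fold, Cyp2b13 at least 4.22-fold and Gga1 at least 2.54-fold higher, the last in 1 of 2 probe sets. In all, 70 genes were higher and 15 lower. The CYP2B, CYP2C and CYP3A list had 8 of 17 higher and 0 lower (10 adjusted over the list alone, list adjusted p = 2.0e-34, 1.4e-06 with an estimated correlation). The other CAR and PXR responsive genes had 5 of 12 higher and 0 lower (9 adjusted over the list alone, list adjusted p = 4.5e-19, 1.6e-05 with an estimated correlation), with Gadd45b at 2.41 ± 0.50 (measured on 1 of 5 control arrays) and Alas1 at 1.59 ± 0.34. Glutathione S-transferases had 5 of 19 higher (6 adjusted over the list alone, list adjusted p = 1.7e-09, 0.010 with an estimated correlation), with Gstt3 at 1.88 ± 0.36 and Gstm3 at 1.88 ± 0.12. UDP-glucuronosyltransferases and sulfotransferases had 3 of 18 higher (5 adjusted over the list alone, list adjusted p = 5.4e-09, 1.1e-04 with an estimated correlation). AHR responsive genes had 2 of 8 higher (2 and 1 lower adjusted over the list alone, list adjusted p = 0.019, 0.044 with an estimated correlation). PPAR-alpha targets lay lower with 0 of 25 called (6 lower adjusted over the list alone, list adjusted p = 6.9e-11, 0.017 with an estimated correlation). Male-biased genes had 0 of 12 called (list adjusted p = 0.83), and female-biased genes had Cyp2b9 and Cyp2b13 higher (3 adjusted over the list alone, list adjusted p = 0.066). The gluconeogenesis list lay lower (adjusted p = 0.021, 0.19 with an estimated correlation). The unfolded protein response (0.0080, then 0.49), acute phase (0.0042, then 0.52), Kupffer cell (0.0043, then 0.52) and lymphocyte lists (0.010, then 0.16) lay higher. Of these 5 lists' members Crp and, below background, Nkg7 were called. The largest falls with a measured level were Rdh16f2 (-2.06 ± 0.45, adjusted p = 0.022), the acyl-CoA synthetase Acsl4 (-0.56 ± 0.12) and Hsdl2 (-0.39 ± 0.09). Dnhd1 (1 of 2 probe sets) and Spns3 were at least 1.14-fold and 1.05-fold lower, on 4 and 3 of 5 control arrays, and Kcng2, Cox6b2 and Deup1 were below background in both groups. With 1 array left out the calls of Gga1 (adjusted p = 0.081), Rdh16f2 (0.089), Alas1 (0.086) and the unfolded protein list (0.15) ended without control replicate 2. Those of Acsl4 (0.087), Gadd45b (0.056) and Crp (0.14) ended without control replicate 4, and of Hsdl2 (0.11) without control replicate 5. Of treated animals, those lost were Nkg7 (0.099) without replicate 4, the gluconeogenesis list (0.17) without replicate 2 and the Kupffer cell list (0.068) without replicate 5. The count of 85 fell to 52 without control replicate 1, and was 121, with all 85 among them, without the conazole array with the 3′ excess. The fit on the 10 arrays compared called 276.

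**Figure D2:**
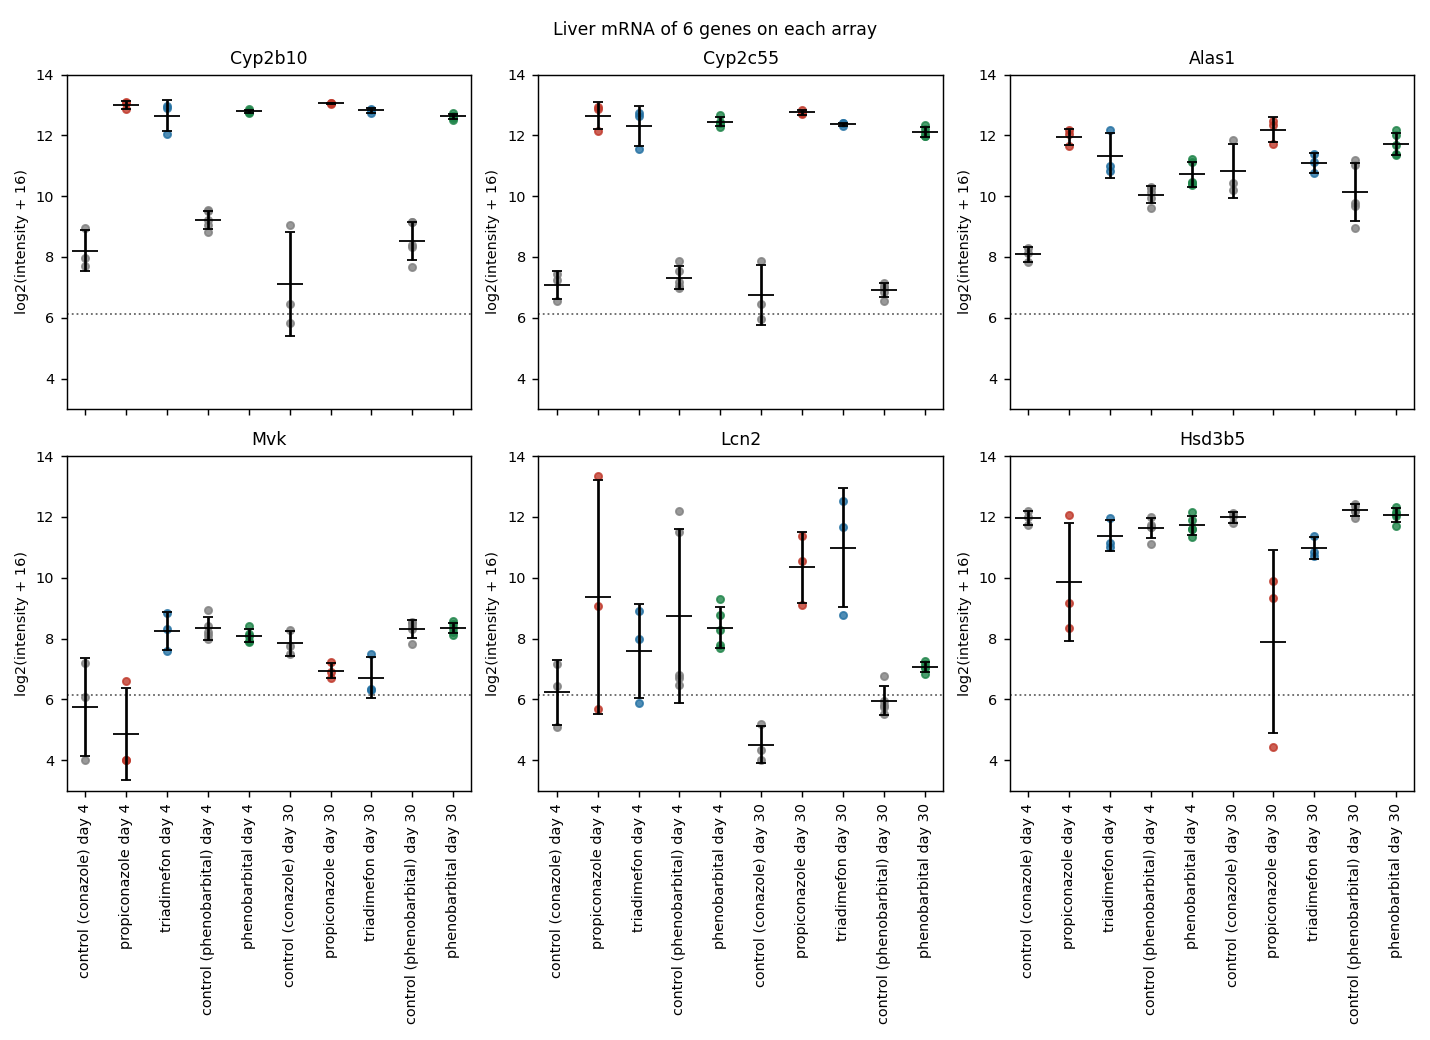
Expression, log2(intensity + 16), of Cyp2b10, Cyp2c55, Alas1, Mvk, Lcn2 and Hsd3b5 in the 10 groups, 1 point per array with the group mean and SD (n = 3 or 5). The dotted line is background, 6.13. Cyp2b10 and Cyp2c55 are higher in every treated group than in its controls.

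A list not described for a comparison with controls did not pass there. The remaining lists did not pass in any of these 6 comparisons. Of 19 hepatic transporters 4 rose and 3 fell under propiconazole on day 4 and 5 and 1 on day 30, 2 and 0, then 5 and 1, under triadimefon, and 1 and 1, then 1 and 0, under phenobarbital. Of 21 retinoid metabolism genes 5 rose and 4 fell (4 and 0 without the array with the 3′ excess), then 4 and 2, under propiconazole, 1 and 0, then 2 and 1, under triadimefon, and 0, then 2 and 0, under phenobarbital. Cyp26a1 rose under propiconazole (2.39 ± 0.48 and 1.73 ± 0.48 on days 4 and 30), on both days under triadimefon (2.83 ± 0.48 on day 30) and on day 30 under phenobarbital (1.65 ± 0.37). Circadian clock genes (17 measured) had 2 lower under propiconazole on day 4, Cry2 (-1.57 ± 0.34, on 2 of 3 treated arrays, but -0.86 without replicate 2) and Hlf (-1.14 ± 0.20), and 3 lower on day 30. Of 11 periportal markers 1 and 2 fell under propiconazole on days 4 and 30, with the histidine lyase Hal at -1.01 ± 0.18 and -0.84 ± 0.18, and Hal alone on day 30 under triadimefon (-0.75 ± 0.18). Of 13 hepatocyte secretory proteins 3 fell under propiconazole on day 4, and 1 without replicate 2. Of 9 neutrophil and myeloid precursor markers S100a8 alone was called, under propiconazole on both days and triadimefon on day 30. Without the array with the 3′ excess these counts were 0, 1 and 3. Stellate cell and fibroblast markers (13) had 1 higher and 1 lower under propiconazole on day 4, 3 lower on day 30 and 1 higher under triadimefon on day 4. Cholangiocyte and progenitor markers (9) had Sox9 and Epcam higher under propiconazole on both days and Sox9 under triadimefon and phenobarbital on day 4 (Sox9 in 1 or 2 of 3 probe sets, Epcam on day 30 in 1 of 2). Of these calls only Sox9 on day 30 held with each array left out. Lost were Sox9 (0.61, adjusted p = 0.26, replicate 1) and Epcam (0.17, control replicate 1) under propiconazole on day 4, Epcam on day 30 (0.088, replicate 2), and Sox9 under triadimefon (0.072, control replicate 2) and phenobarbital (0.14, replicate 3). Under propiconazole Sox9 on day 4 turned to -0.1762 with the mean of probe sets, and Epcam on day 30 turned to -0.3325 without _x_at and _s_at probe sets. Erythroid markers (6) had 1 higher under triadimefon on day 30, and adipocyte markers (8) 1 higher under each conazole on day 4. The other comparisons of these 10 lists had 0 calls, and the lowest list adjusted p was 0.055. Single arrays also ended the calls of Cyp26a1 under propiconazole on day 30 (adjusted p = 0.12, propiconazole replicate 2) and under phenobarbital (0.13, control replicate 2), and of Hal under triadimefon (0.062, control replicate 2).

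**Figure D3:**
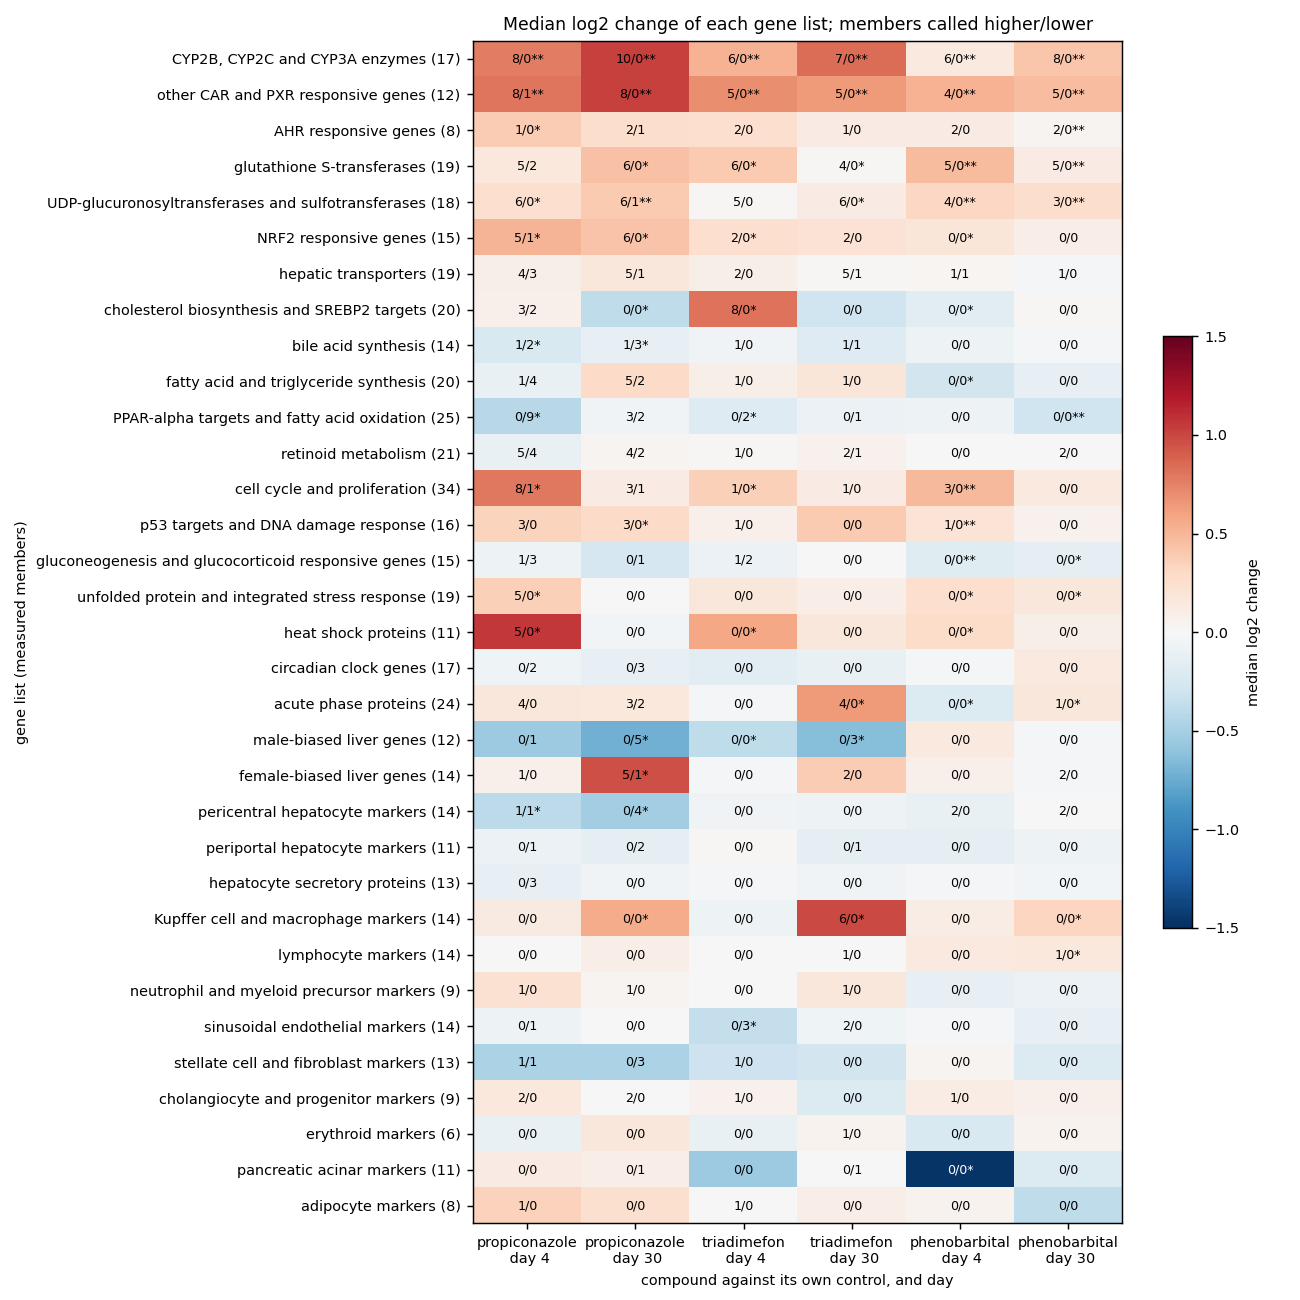
The 33 gene lists (vertical) in each compound's comparison with controls on days 4 and 30 (horizontal). Colour is the median log2 change of a list's measured genes, each cell gives the members called higher and lower, 1 star marks a list adjusted p under 0.05 and 2 stars one that also held with an estimated correlation. The CYP2B, CYP2C and CYP3A list and the other CAR and PXR responsive genes carry 2 stars in all 6 comparisons.

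Propiconazole and triadimefon were compared directly. On day 4 propiconazole livers had higher Cyp2c65 (8.8 against 6.5, 2.25 ± 0.41, adjusted p = 0.0042, 95% interval 1.41 to 3.08, but 1.49 without triadimefon replicate 3) and lower Mvk (4.87 ± 1.51 against 8.25 ± 0.64, -3.38 ± 0.54, adjusted p = 0.0017) than triadimefon livers, Mvk being measured on 1 of 3 propiconazole and Cyp2c65 on 2 of 3 triadimefon arrays. Il1r1 was higher by 2.69 ± 0.58 (on 1 of 3 triadimefon arrays), the hyaluronan synthase Has1 and the retinoic acid receptor Rarg (on 1 of 3 propiconazole arrays) at least 1.32-fold and 1.22-fold. Fam20a and Trappc12 were lower (-2.47 ± 0.61 and -2.23 ± 0.52, both on 1 of 3 propiconazole arrays), Srcin1 at least 1.33-fold (on 2 of 3 triadimefon arrays). Pak4 (higher) and Trim75 (lower) had means below background. In all, 174 genes were higher and 152 lower (92 and 5953 as deposited). The induction of Cyp2b10 (0.36 ± 0.45, 95% interval -0.55 to 1.28), Cyp2c55 (0.34 ± 0.32, -0.31 to 0.98), Alas1 (0.61, -0.27 to 1.5) and Gstm3 (0.08, -0.24 to 0.39) did not differ by the test. The cholesterol biosynthesis list was lower under propiconazole (2 of 20 called, 10 adjusted over the list alone, list adjusted p = 1.5e-09). PPAR-alpha targets were also lower (2 of 25 called, 5 adjusted over the list alone, list adjusted p = 0.0080), as were bile acid synthesis (1 of 14, 0.027), fatty acid and triglyceride synthesis (0 called, 0.032) and pericentral markers (1 of 14, 0.032). Heat shock proteins (0 called, 0.031) and sinusoidal endothelial markers (0 called, 0.024) were higher. With an estimated correlation the cholesterol list stood at adjusted p = 0.52 and the others at 0.57. Without the array with the 3′ excess 157 genes were called, of which 71 were among the 326, and Il1r1 (adjusted p = 0.066), Rarg (0.070), Pak4 (0.28), Fam20a (0.18), Trappc12 (0.15) and Srcin1 (0.17) were not. Single arrays ended the calls of all these lists but cholesterol biosynthesis (up to adjusted p = 0.065 for PPAR-alpha targets, 0.13 for sinusoidal markers, 0.17 for bile acids, 0.27 for heat shock proteins, 0.29 for fatty acid synthesis and 0.30 for pericentral markers). The count ran from 100 without triadimefon replicate 1 to 2218 and 2343 without propiconazole replicates 1 and 3, and limma on the 6 arrays alone called 0 genes, against 646 at an unadjusted p under 0.05.

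On day 30, 394 genes were higher and 298 lower in propiconazole than in triadimefon livers. Cyp2b13 was higher by 3.23 ± 0.56 (adjusted p = 8.9e-04, measured on 2 of 3 triadimefon arrays), the serine protease Prss8 at least 4.46-fold, Lratd1 at least 3.25-fold, the receptor Fgfrl1 by 2.98 ± 0.78 (on 1 of 3 triadimefon arrays) and Cbr3 at least 1.88-fold on 2 of 3 arrays. Hsd3b5 was lower (-3.08 ± 0.77, adjusted p = 0.019, on 2 of 3 propiconazole arrays). So were the chromatin reader Zmynd8 (at least 2.80-fold, adjusted p = 3.8e-05), Wfdc2 (at least 2.10-fold), Mcm3ap (at least 1.48-fold) and the flippase Atp11a (-2.45 ± 0.55, on 2 of 3 propiconazole arrays). NRF2 responsive genes were higher under propiconazole (2 of 15 called, 3 adjusted over the list alone, list adjusted p = 0.0050), with Abcc4 at 2.22 ± 0.53, and so were female-biased genes (1 of 14, 0.044). Pericentral markers (2 of 14, 0.0043), with Oat at -1.73 ± 0.31, the acute phase proteins (0, 1.3e-04) and the Kupffer cell list (0, 0.0077) were lower, and all 5 lists stood at adjusted p = 0.70 with an estimated correlation. Cyp2b10 (0.23 ± 0.45, 95% interval -0.68 to 1.14) and Cyp2c55 (0.40, -0.25 to 1.04) did not differ by the test. Single arrays ended the calls of Fgfrl1 (adjusted p = 0.16) and the Kupffer list (0.59) without triadimefon replicate 1, and of Atp11a (0.075) without its replicate 3. Without propiconazole replicate 3 Prss8 (0.087), Hsd3b5 (-1.36, 0.19) and the female-biased list (0.39) were lost, and without its replicate 1 Cbr3 (0.051) and the NRF2 (0.085) and pericentral lists (0.087). The count of 692 fell to 415, 423 and 450 without triadimefon replicate 3, propiconazole replicate 3 and triadimefon replicate 1. It was 1157, with all 692 among them, without the day 4 array with the 3′ excess, and 10 on the 6 arrays alone.

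Whether each compound's change differed between days was tested directly. The Actb 3′ excess in conazole controls was 1.12 on day 4 and 0.40 on day 30. In these and the following differences of changes, genes at or below background in a group depend on the floor of the scale, and their fitted sizes are no measured folds. For propiconazole 126 genes had a higher and 219 a lower change on day 30 than on day 4, a balance that turned as deposited (79 and 20) and with median centring (50 and 40). Ppargc1b (3.50 ± 0.60), Fbxw9 (4.36 ± 0.81), Ano6 (4.14 ± 0.77), Cyp2b13 (3.95 ± 0.79) and Atg16l2 (3.77 ± 0.93) were highest, and Obp2a (-5.18 ± 1.09), Susd4 (-3.99 ± 0.64), Lama3 (-2.81 ± 0.54), Rmnd5b (-2.80 ± 0.67) and Ces4a (-2.73 ± 0.60) lowest, each with some group at or below background. Ddit3 (-2.33 ± 0.43) and Alas1 (-2.49 ± 0.61) also had a lower change on day 30. PPAR-alpha targets moved up (3 of 25 called, 5 adjusted over the list alone, list adjusted p = 5.1e-05, 0.52 with an estimated correlation). Heat shock proteins moved down (0 called, 9 adjusted over the list alone, list adjusted p = 8.4e-05, 0.71 with an estimated correlation). For triadimefon 87 genes had a higher and 145 a lower change on day 30 (42 and 381 as deposited, 44 and 128 with median centring). Mvk (-3.62 ± 0.76), Inhba, Alas1 (-2.98 ± 0.61), Armc6 and Necap2 were lowest, and Il1r1, Neurl4, Fbxw9, Cnga2 and Mnt highest. Of 20 cholesterol biosynthesis genes 5 had a lower change (12 adjusted over the list alone, list adjusted p = 3.0e-10, 0.42 with an estimated correlation), including Idi1 (-1.67 ± 0.40). The Kupffer cell list (0 called, 9 adjusted over the list alone, list adjusted p = 3.9e-08, 0.54 with an estimated correlation) and the acute phase list (0 called, 3.9e-06, 0.89 with an estimated correlation) moved up. For phenobarbital limma called 1 gene, the predicted gene Gm1673 (2.63 ± 0.43, adjusted p = 0.016), outside the naming rule and chosen after its value was seen, against 481 genes at an unadjusted p under 0.05. Cell cycle genes moved down (0 called, 2 adjusted over the list alone, list adjusted p = 1.4e-09) and acute phase proteins up (0 called, 9.2e-09), both at 0.29 with an estimated correlation. Single arrays ended the calls of Atg16l2 (adjusted p = 0.068, propiconazole day 4 replicate 2), Rmnd5b (0.083, control day 4 replicate 2), and Ces4a (0.052, propiconazole day 30 replicate 3) for propiconazole. For triadimefon they ended those of Neurl4 (0.090, triadimefon day 4 replicate 1), Fbxw9 (0.13, control day 30 replicate 2) and Inhba (0.094, triadimefon day 30 replicate 3). Without the array with the 3′ excess the counts were 520, 601 and 1, of which 233, 232 and 1 were among the 345, 232 and 1. On the arrays of each compound and its controls alone limma called 0 genes for propiconazole, against 1158 at an unadjusted p under 0.05, only Tprn for triadimefon (adjusted p = 0.027) and only Moxd1 for phenobarbital (adjusted p = 2.4e-04).

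The conazole changes were then compared with the phenobarbital change on the same day, at unequal doses and across experiments. Propiconazole on day 4 gave 325 genes another change than phenobarbital, 52.9% of them a higher one (12 higher and 417 lower as deposited, 34 and 113 with median centring). Alas1 (3.19 ± 0.55, adjusted p = 0.0051), the salt-regulating kinase Sgk1 (1.95 ± 0.39), Atf3 (1.95 ± 0.52), Golt1b and Rmnd5b were highest, and Ppargc1b (-3.43 ± 0.54, adjusted p = 0.0020), Fbxw9, Neurl4, Efcab6 and Arap1 lowest, with Ppara at -1.83 ± 0.41. PPAR-alpha targets moved down relative to phenobarbital (2 of 25 called, 8 adjusted over the list alone, list adjusted p = 3.6e-05) and heat shock proteins up (0 called, 2 adjusted over the list alone, 0.0017), both at 0.76 with an estimated correlation. Cyp2b10 (1.24 ± 0.57, 95% interval 0.09 to 2.39, adjusted p = 0.24) and Cyp2c55 (0.45, -0.37 to 1.27) did not pass. On day 30 the changes of 340 genes differed, 51.5% of them higher (56 higher and 79 lower as deposited, 66 and 133 with median centring). Abcc4 (3.79 ± 0.67), the transcription factor Sox4 (3.03 ± 0.28, adjusted p = 1.3e-07), Slco1a4 (2.77 ± 0.73), Sult2a2 and Atg16l2 were highest, and Moxd1 (-7.75 ± 1.32), Susd4 (-4.38 ± 0.58, adjusted p = 8.4e-05), Hsd3b5 (-3.92 ± 0.98), Obp2a and Sh3bp5l lowest. Male-biased genes moved down (2 of 12 called, 5 adjusted over the list alone, list adjusted p = 1.2e-05) and so did pericentral markers (1 of 14, 6 adjusted over the list alone, 3.6e-05), both at adjusted p = 0.24 with an estimated correlation. NRF2 responsive genes moved up (1 of 15, 4 adjusted over the list alone, 1.7e-04, 0.30 with an estimated correlation). Cyp2b10 (1.85 ± 0.57, 0.70 to 3.01, adjusted p = 0.083) did not pass. On day 4 single arrays ended the calls of Golt1b (adjusted p = 0.12, propiconazole replicate 2, without which Rmnd5b, Atf3, Neurl4 and Arap1 were lost too), Rmnd5b (0.15), Atf3 (0.12, and 1.28 without propiconazole replicate 1), Neurl4 (0.14) and Efcab6 (0.070, all control replicate 2), Fbxw9 (0.053) and Arap1 (0.098, both control replicate 1). On day 30 they ended those of Atg16l2 (0.074), Sult2a2 (0.075), Hsd3b5 (-2.2, 0.082) and Sh3bp5l (0.11, all propiconazole replicate 3), Slco1a4 (0.14) and Obp2a (0.092, both control replicate 1). Without the array with the 3′ excess 170 and 770 genes were called, of which 108 and 340 were among the 325 and 340, and on the arrays compared alone 14 and 974.

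Triadimefon differed from phenobarbital in 8 genes on day 4, 4 higher and 4 lower (152 and 11 as deposited, 31 and 9 with median centring): Slc5a10 (1.99 ± 0.34), Spata16, Cyp4f39, Strap (0.66 ± 0.11), Itpkb, Plcb3 (-2.22 ± 0.35), Grik4 and 1700061N14Rik (-1.84 ± 0.31), the last outside the naming rule and chosen after its value was seen. Cyp4f39 (adjusted p = 0.097, triadimefon replicate 1), Itpkb (0.055, control replicate 1) and Grik4 (0.080, phenobarbital control replicate 1) were lost with 1 array left out. The cholesterol biosynthesis list moved up relative to phenobarbital (0 of 20 called, 13 adjusted over the list alone, list adjusted p = 3.3e-15, 0.10 with an estimated correlation). The sinusoidal endothelial list (0 called, 3 adjusted over the list alone, list adjusted p = 3.0e-04, 0.67 with an estimated correlation) and the male-biased list (0 called, 0.0067, 0.88 with an estimated correlation) moved down. On day 30, 33 genes had a higher and 47 a lower change (4 and 9 as deposited, 4 and 21 with median centring). Highest were Arrdc1 (2.57 ± 0.60), Fndc11, S100b (1.76 ± 0.32), the ceramide synthase Cers6 (1.73 ± 0.38) and Adam4. Lowest were Aldh3b2 (-2.70 ± 0.55), Cyp2u1 (-2.60 ± 0.54), Susd4 (-2.41 ± 0.58), Armc6 (-2.38 ± 0.43) and the growth factor Vegfb (-2.28 ± 0.52). Of these, S100b and Armc6 kept their call with every single array left out, while the others reached an adjusted p of 0.055 to 0.14. The male-biased list moved down (1 of 12 called, list adjusted p = 6.4e-04), and the Kupffer cell (0 called, 3 adjusted over the list alone, 6.7e-05) and acute phase lists (0 called, 0.0016) up. All 3 stood at adjusted p = 0.73 with an estimated correlation. Without the array with the 3′ excess 98 and 370 genes were called, all 8 and 80 among them, and on the arrays compared alone 155 and 589.

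Calls overlapped between compounds. On day 4, 232 genes were higher and 173 lower under both conazoles, against 27.5 and 19.1 for independent lists of those sizes, and on day 30, 227 and 237, against 22.6 and 29.4. Of the genes higher under phenobarbital, propiconazole shared 58 of 94 on day 4 and 48 of 70 on day 30 (6.92 and 3.70 for independent lists), and triadimefon 35 and 39 (1.98 and 1.69). The conazoles shared their controls. Simulated unchanged groups against them gave a correlation of changes across genes of 0.50 on both days, against 0.61 and 0.64 observed. The covariance was 0.042, against 0.13 and 0.15. In 100 simulations equal numbers of top genes overlapped by 145.6 (higher) and 109.7 (lower) on day 4 and 132.2 and 160.6 on day 30. Calls overlapped by 0 there, uninformative as no gene was changed (405 and 464 observed). Part of the overlap may come from the shared controls, and 3 are too few to split. Changes under a conazole and under phenobarbital, which share no animals, correlated across genes at 0.27 and 0.31 for propiconazole and 0.25 and 0.29 for triadimefon on days 4 and 30, where genes are not independent replicates.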

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

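The tests of 3′ signal, an undosed animal, the spread under phenobarbital, a single animal and neutrophils, and the splits with each factor's own effect removed, were chosen after the results were seen. The first form of the phenobarbital test covered both days, and earlier forms of the neutrophil test used its other markers, several of them near the floor. The first single-animal test used genes picked for the pattern and was dropped.

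The changes on day 30 and day 4 differed by the test of the difference itself in 345 genes for propiconazole, 232 for triadimefon and 1 for phenobarbital. Of 100 splits of the arrays, 17, 6 and 14 gave as many, with up to 3685, 1417 and 6 genes. Splits also mix each compound's own effect into the groups, so these counts neither exclude chance nor show a structure of the samples. With those effects removed first, 9, 1 and 16 of 100 gave as many, with up to 754, 66 and 3 genes in other splits.

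In groups of 5, where chance marks about 1 in 20 tests, 4 of 56 had 1 array whose gap to the next passed Dixon's limit at 95%, as a share of the group's range. They were the Gapdh 3′ excess of phenobarbital control day 30 replicate 3 (0.739, highest), Gadd45b in phenobarbital day 4 replicate 2 (0.783, highest), and Gga1 (0.737) and Hsdl2 (0.848) in phenobarbital day 30 replicate 1 (lowest). Of 9568 further probe sets without a single gene symbol, tested apart, 322 and 310 were called higher and 298 and 190 lower under propiconazole on days 4 and 30, 138 and 109 higher and 97 and 100 lower under triadimefon, and 5 and 11 higher and 1 and 1 lower under phenobarbital.

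Propiconazole day 4 replicate 2 stood apart from its group. An undosed animal is argued against, since Cyp2b10 and Cyp2c55 lay at least 4.142 log2 units above the highest control array. RNA kept or copied mainly at its 3′ end remains a candidate explanation: the array had the largest 3′ excess of Gapdh (6.399), Actb and Pcx, although Tfrc, with the lowest, goes against it. RNA of another cell type stays open, because the Kupffer cell list deviated most, by a median of 0.5156, near the bound of 0.5 set before, while the abundant macrophage transcripts C1qa (4.0) and C1qb (5.45) were low.

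In the shared fit fewer genes were called under phenobarbital than under either conazole. A wider spread or fewer arrays under phenobarbital is argued against: it had 5 arrays per group against 3, and the SD between them was 0.7766 of the lower conazole's on day 4 and 0.6563 on day 30 (at most 0.8094 and 0.6879 with any 1 array left out). On the arrays compared alone the order changed, with 330 under phenobarbital against 6 and 1 on day 4 and 276 against 541 and 118 on day 30. If the 1 spread shared by all groups alone caused the lower count, changes net of each group's own spread would be as large under phenobarbital. On day 30 their SD was 0.5706 of the lower conazole's, 0.506 to 0.637 with any 1 array left out. That argues against the shared spread as the only cause, not as part of it. On day 4 the ratio was 0.7216 (0.556 to 0.945), so the shared spread and the size of change cannot be told apart. The unequal doses of the design stay open as an untested explanation.

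On day 30 S100a8 was higher under both conazoles and the acute phase list under triadimefon. A rise carried by 1 triadimefon animal is argued against, since the list passed with each left out (adjusted p at most 7.005e-04). With an estimated correlation it did not (0.40). The S100a8 call ended without propiconazole replicate 2 (0.083) but held under triadimefon with each array left out. Blood neutrophils would bring S100a9 beside S100a8. S100a9 changed less, by -4.134 and -3.04 (± 1.57 each) for propiconazole and triadimefon, but within 2 errors of the 1 unit allowed. The 8 other neutrophil markers had a median change of 0.0232 and 0.0829, against neutrophils. Yet several are precursor transcripts or near the floor, and 5 exceeded background in some group. Without the array with the 3′ excess 3 of all 9 rose under triadimefon. Neutrophils and a response of the liver stay open.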

How the results depend on the processing

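Chosen after the data were seen were normalization within each experiment, the fits without propiconazole day 4 replicate 2 and list tests with each array left out. No called list changed direction under the 7 alternatives run on lists. Of 77 list calls in the comparisons with controls and between conazoles, 22 held with an estimated correlation, 69 with values as deposited, 66 with the mean of probe sets, 72 with the arrays compared alone and 77 with the block, and 482 of 562 with 1 array left out. Of 280 calls of named genes 232 held with values as deposited, 240 with median centring, 241 with the mean of probe sets, 229 with the block, 208 with array weights, 129 with the arrays compared alone, and 1867 of 2386 with 1 array left out. Sox9 reversed with the mean of probe sets (-0.1762) and Epcam without _x_at and _s_at probe sets (-0.3325). The cause was not tested for any value below, except where fewer arrays or genes entered. Signal over background limits what was measurable to 9313 of 17728 genes.

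Values as deposited gave 1067 genes for propiconazole day 30, 1659 and 393 for triadimefon, 6045 and 277 for propiconazole against triadimefon, 99 and 423 for the day differences of propiconazole and triadimefon, 135 for propiconazole minus phenobarbital day 30, and 163 and 13 for triadimefon minus phenobarbital. They moved the median change of all genes by -0.158, 0.170 and -0.377 for propiconazole, triadimefon and their difference on day 4. Overlaps of the conazoles were 223 and 197, and of propiconazole with phenobarbital on day 4 42. Median centring gave 1260 (propiconazole day 30), 496 (triadimefon day 30), 3093 and 365 (propiconazole against triadimefon), 90 (day difference of propiconazole), 1.5e+02 and 199 (propiconazole minus phenobarbital) and 40 and 25 (triadimefon minus phenobarbital). Normalization within each experiment gave 1.8e+02 (phenobarbital day 4), 157 (propiconazole against triadimefon day 4), 201 and 110 (day differences of the conazoles), 221 (propiconazole minus phenobarbital day 30) and 31 (triadimefon minus phenobarbital day 30).

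The arrays compared alone gave 6 and 541 for propiconazole, 1 and 118 for triadimefon, 330 and 276 for phenobarbital, 0 and 10 for propiconazole against triadimefon, 0 and 1 for the conazole day differences, and 14, 974, 155 and 589 for the differences from phenobarbital. Without propiconazole day 4 replicate 2 as well these were 8 (propiconazole day 4), 0 (propiconazole against triadimefon), 3 (day difference) and 137 (minus phenobarbital). Without that array in the shared fit counts were 1270 and 1699 (triadimefon), 248 (phenobarbital day 4), 1157 (propiconazole against triadimefon day 30), 601 (day difference of triadimefon), 770 (propiconazole minus phenobarbital day 30) and 98 and 370 (triadimefon minus phenobarbital), and overlaps 623 and 888 (conazoles) and 75 (triadimefon and phenobarbital day 4). Array weights gave 98 (propiconazole day 4), 829 and 601 (phenobarbital), 4 (propiconazole against triadimefon day 4), 27, 1.5e+02 and 2 (day differences) and 8, 697, 49 and 314 (differences from phenobarbital). Every probe set gave 499 (propiconazole against triadimefon day 4), 593 and 3 (day differences of propiconazole and phenobarbital) and 41 and 140 (triadimefon minus phenobarbital). The mean of probe sets gave 143 (day difference of triadimefon) and, for triadimefon minus phenobarbital day 4, 15, a pseudocount of 64 14 and leaving out the lowest 40% 1. Both filters on dim genes left 0 for the day difference of phenobarbital. At an adjusted p under 0.01 the overlaps were 105, 25 and 18 on day 4 and 1.5e+02, 26 and 20 on day 30.

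Replicate numbers do not pair the samples: same-numbered arrays correlated at -0.106 to 0.159, over 0.1 in 4 of 28 pairs, and 6 were best with their own number. The replicate block gave 416 (triadimefon day 4), 135 and 460 (propiconazole against triadimefon), 1.5e+02, 99 and 0 (day differences), 108 and 203 (propiconazole minus phenobarbital) and 0 and 27 (triadimefon minus phenobarbital), and changed no other count by over 1.5 times.

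With 1 array left out counts ran from 1526 to 3856 and 1277 to 1772 for propiconazole on days 4 and 30, 215 to 850 and 502 to 895 for triadimefon, 65 to 141 and 52 to 73 for phenobarbital, 100 to 2343 and 415 to 669 for propiconazole against triadimefon, 180 to 1233, 97 to 319 and 0 to 2 for the day differences, 112 to 1846 and 204 to 523 for propiconazole minus phenobarbital, and 6 to 45 and 29 to 92 for triadimefon minus phenobarbital. A group left with 2 arrays shares the spread of the others.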

Other observations

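The splits of the arrays were set before their results were seen, and those with each factor's own effect removed after.

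Lcn2 was high in some untreated animals too. Among day 4 phenobarbital controls it stood at 11.5 and 12.2 on replicates 1 and 2 and at 6.48 to 6.79 on the other 3, and at 13.4, 9.08 and 5.67 in the propiconazole day 4 animals.

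The fall of male-biased liver genes on day 30 was set against the phenobarbital effect by the difference of changes. The list was lower for propiconazole and triadimefon (adjusted p = 1.238e-05 and 6.43e-04). Neither held with an estimated correlation (0.24 and 0.73), and experiment and compound are confounded. The list did not pass under phenobarbital, so the difference mostly repeats its fall under the conazoles and is no independent test. That the fall is specific to the conazoles at these doses stays a hypothesis.

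Other splits of the arrays were refitted for each count. For phenobarbital against control 1 of 100 splits, the real one, gave as many genes (120 and 85, highest others 6 and 3). Chance is thus unlikely. The conazole groups of 3 allow 10 splits, too few: the real counts were 2463, 1917, 665 and 958 for propiconazole and triadimefon on days 4 and 30, the highest others 1052, 171, 30 and 44. For propiconazole against triadimefon they were 326 and 692, against 1474 and 157. On day 4, 5 of the 10 splits gave as many, and the highest, several times the real count, points to a structure of the samples. For the differences from phenobarbital, 6 and 9 of 100 splits gave as many for propiconazole (325 and 340, highest others 1927 and 870). For triadimefon 6 and 9 did (8 and 80, highest others 106 and 280). These splits mix in each compound's own effect and cannot exclude chance. With each factor's own effect removed first, 1, 1, 2 and 1 of 100 gave as many, the highest others being 225, 33, 10 and 6.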
